A study of Homo sapiens with 12 samples.

How the data were processed

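Gene expression was measured in HCT116 cells, an established human colorectal carcinoma line, on 12 arrays of 1-colour Agilent design, with 1 array for each of 12 total RNA samples labelled with Cy3. The samples formed 4 groups of 3: cells given DMSO for 24 h, cells given 1 µM E7820 for 24 h, cells transfected with 20 nM of a non-target siRNA pool and collected at 48 h, and cells transfected with 20 nM of an siRNA pool against RBM39 and collected at 48 h. Groups and replicate numbers were taken from the sample titles, and doses and times from the labels' protocols and the series' design text. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

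The authors deposited 1 scanner file per array and a value table in log2 units for the series. Per the file headers and the submitters' processing notes, spots were read with Agilent Feature Extraction 11.5.1.1, which subtracts background, removes spatial trends within the array and writes a processed intensity per spot in place of raw brightness. No scaling between arrays had been applied to these intensity values, per the file headers. The deposited table holds log2 values for 36060 probes, with a median of 7.34 in every column. Its columns followed log2 of the processed intensity of the same array, with correlations of 0.9961 to 0.9999 over probes, and column quartiles differed by at most 0.03, as after quantile normalization; the submitters' normalization is not given in the sources used here. It was used only as an alternative.

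Each array held 62976 spots, of which 58717 were not controls and belonged to 50599 probes. Control spots and outlier-flagged spots were left out, and spots of the same probe were averaged. The value of a probe was log2 of the processed intensity minus the array's 75th percentile. The files name probes by accession and not by gene. Accessions were matched, without versions, to a RefSeq gene table of assembly GRCh38.p14, used only for names because the arrays were gridded on hg19. A symbol was found for 28174 probes, on 20503 genes, and 22425 probes stayed unnamed. Probes were kept if well above background on all 3 arrays of at least 1 group. This left 28423 probes, 20386 of them with a symbol, and each of 15188 genes was represented by its probe with the highest mean. On 11 arrays 52.2% to 63.8% of probes were well above background, and on siRBM39 replicate 2 the share was 45.9%. The number of arrays, 3 per group, limits the precision of every value.

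All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit on group means, then eBayes), with contrasts of E7820 against DMSO, of siRBM39 against non-target siRNA, and of the difference of these log2 fold changes (siRBM39 minus E7820). P-values were adjusted by Benjamini-Hochberg over the genes tested and called at 0.05. An exact permutation test of 3 against 3 arrays could not fall under p = 0.1. Counts are also given with an absolute log2 fold change of at least 1. Errors after ± are standard errors of the fit with n = 3 arrays per group, unless marked SD. The 2 contrasts use separate controls. The median residual SD was 0.166 on the log2 scale.

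Where a gene was not well above background on any array of a group, its fold change is given as a bound: the mean of the brighter group over the mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. No fold is given where that ratio lies under 1 or where both groups are below background. Gene lists, 30 in number with 683 members, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Members are counted as called over all genes tested and as called when adjusted over the list alone. The lists covered RBM39 and its ligase, SR proteins, U2 snRNP and 3' splice site factors, hnRNP proteins, nonsense-mediated decay, the cell cycle, DNA repair, histones, p53, ATF4, endoplasmic reticulum stress, interferon, NF-kappaB, AP-1, integrins, Wnt, epithelial markers, fibroblast, endothelial and blood cell markers, cholesterol, hypoxia, AHR, NRF2, carbonic anhydrases, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, apoptosis, heat shock and RNA interference. Of the members tested, 9 stood in more than 1 list. Probes of the same gene were compared with limma's diffSplice, using the gene-level F test, over 3963 genes with at least 2 kept probes.

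The groups, tests, gene lists and rule for naming genes were fixed before the data were examined. The rule took, per treatment, the 8 called genes with the largest rise and the 8 with the largest fall whose groups did not overlap, and up to 4 called members per list. It also took the 5 genes per direction with the largest shared change, the 6 per direction with the largest difference, 5 genes for probe usage, and always RBM39, RBM23, DCAF15, DDB1, DDA1, CUL4A and ITGA2. Results for some single genes, with 1 test of an explanation that rested on them, are not reported here. Every gene reported as changed had all 3 treated arrays on the same side of all 3 control arrays.

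Deviations from the group means of arrays with the same replicate number correlated across genes. The values were 0.305 to 0.765 for E7820 with DMSO and 0.267 to 0.716 for siRBM39 with non-target siRNA. For numbers 1 and 2 the highest correlation with another number was larger than that with the same number. It was 0.603 and 0.316 for E7820 (same number 0.572 and 0.305), and 0.277 and 0.3 for siRBM39 (0.27 and 0.267). Only number 3 stood apart, so numbers 1 and 2 did not mark pairs. Replicates 1 and 2 of every group lay on slide 1 and replicate 3 on slide 2, scanned separately. After removal of the slide means the correlations within numbers were -0.328 to 0.102. Slide 2 held replicate 3 alone, so the slide and anything else shared by the arrays of number 3 cannot be told apart as their source. Slide and replicate number were each fitted as a block as alternatives.

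Other alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the array median, no filter on dim probes, probes well above background on all 12 arrays, the 6 arrays of a contrast alone, the mean of a gene's probes, limma's trend and robust options, the deposited log2 table, estimated inter-gene correlation and fry for the lists, and each array left out in turn. The normexp alternative used median spot signals because the files hold no mean signals. Fry was used in its directional form, which asks whether the genes of a list moved in 1 direction on average, without regard to other genes. A list whose members moved both ways can therefore fail it. Camera asks whether the genes of a list changed more than other genes. Their p-values therefore answer different questions. Chosen after the data were seen were scaling to the mean of 7 spike-in probes with a mean log2 intensity over 7, slide 1 alone, and every kept probe as its own row.

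Each step was tested on simulated data built from the real means and spread, with known changes. Noise was drawn independently for each gene and array, with no slide effect and no correlation between genes. The simulation therefore cannot show how often the list test makes false calls when genes are correlated. At log2 changes of 0.5, 1 and 2, calls recovered 38.8%, 73.1% and 95.5% of the changed genes for E7820, 200 in all among 15096 tested, and 5.48% of the calls were false. For siRBM39 the shares were 32.4%, 75.8% and 98.5%, with 3.52% of calls false, and for the difference 14.9%, 61.2% and 83.3%, with 2.75% of calls false. The probe comparison, simulated with a change in E7820 alone, recovered 73% of 200 genes with 1 probe changed by 1 and called 15 unchanged genes. The p53 target list, shifted by 0.5 in siRBM39 alone, was called for siRBM39 and for the difference, and no other list was called. Of 100 genes changed alike in both treatments 62 were called in both. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were handled with data.table (version 1.17.8).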

Results

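HCT116 cells were profiled after a chemical and a genetic perturbation of RBM39 (CAPERα), an RNA-binding protein that acts in pre-mRNA splicing. E7820 is an anticancer aryl sulfonamide that brings RBM39 to the DCAF15 ubiquitin ligase, after which the protein is degraded. Cells received 1 µM E7820 or DMSO for 24 h, or 20 nM of an siRNA pool against RBM39 or of a non-target pool for 48 h. With 3 arrays per group, 15188 genes were tested. On the arrays 45.9% to 63.8% of probes were well above background.

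RBM39 mRNA moved in opposite directions under the treatments. The siRNA pool left 28.1% to 32.6% of the non-target level on the 3 RBM39 probes. On the brightest of them the mean log2 value was 4.16 ± 0.10 (SD, n = 3) with non-target siRNA and 2.55 ± 0.13 (SD, n = 3) with siRBM39, a log2 fold change of -1.62 ± 0.09 (limma, adjusted p = 4.28e-07). With E7820 the same probe rose from 4.19 ± 0.07 in DMSO to 5.15 ± 0.12 (SD, n = 3), a log2 fold change of 0.96 ± 0.09 (adjusted p = 1.1e-05), and the 3 probes rose 1.94-fold to 2.06-fold. The fold changes differed by -2.58 (adjusted p = 2.98e-06).

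**Figure D1:**
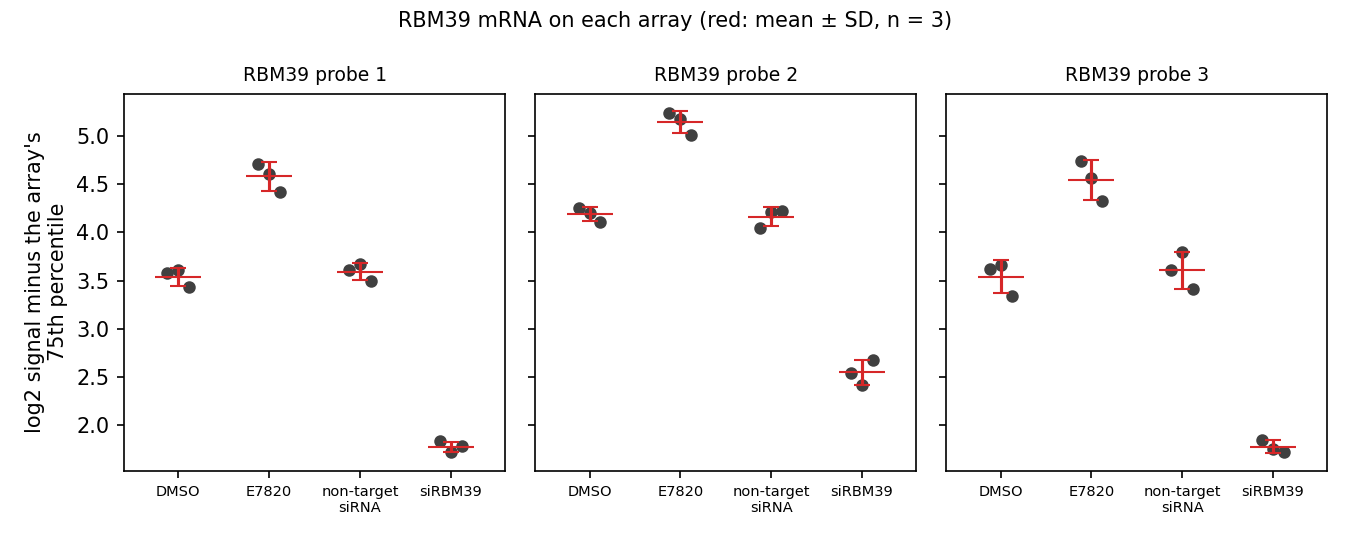
RBM39 signal on each array for 3 probes (y axis, log2 signal minus the array's 75th percentile; red, mean ± SD, n = 3). On every probe the 3 E7820 arrays lie above the DMSO arrays, and the 3 siRBM39 arrays lie below all others.

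RBM23, the paralogue of RBM39 that DCAF15 also binds in the presence of aryl sulfonamides, rose by 0.65 ± 0.12 with E7820 (adjusted p = 0.00081). That call was lost with median centring, and its adjusted p ranged from 2.83e-06 to 0.0767 over the alternatives. RBM23 had a log2 fold change of 0.06 ± 0.12 with siRBM39 (adjusted p = 0.691). With spike-in scaling it passed as lower with siRBM39, at -0.29 (adjusted p = 0.0158). DDB1, the ligase's adaptor, fell by 0.36 ± 0.10 with E7820 (adjusted p = 0.0133), a call lost without DMSO replicate 1, DMSO replicate 2 or E7820 replicate 3 (adjusted p 0.051 to 0.0542). Median centring ended it as well, with a range of 1.93e-05 to 0.0761 over the alternatives. CUL4A, the ligase's scaffold, rose by 0.21 ± 0.08 with siRBM39 (adjusted p = 0.0362). Its call was lost without non-target siRNA replicate 1 or 3 or siRBM39 replicate 1 or 2 (adjusted p 0.062 to 0.135), and with spike-in scaling the value was -0.15 (range of adjusted p over the alternatives, 0.00585 to 0.394). DCAF15 had log2 fold changes of 0.17 ± 0.18 with E7820 (adjusted p = 0.461) and 0.32 ± 0.18 with siRBM39 (adjusted p = 0.174). With slide as a block these passed, at adjusted p = 0.0208 and 0.00076 (ranges over the alternatives, 0.0208 to 0.95 and 0.00076 to 0.828), but they fell to 0.03 with median centring and -0.04 with spike-in scaling. DDA1 did not pass in either contrast (-0.03 ± 0.17 and 0.10 ± 0.17, the latter -0.26 with spike-in scaling). ITGA2, the integrin α2 gene, fell by 1.75 ± 0.43 with siRBM39 (adjusted p = 0.00607), partly below background in that group, or by 0.91 with normexp. With E7820 it had a value of -0.82 ± 0.43, or -0.24 with normexp (adjusted p = 0.139, and 0.000525 with slide as a block; range over the alternatives, 0.000525 to 0.275).

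The comparison of E7820 with DMSO asked which transcripts change when RBM39 is degraded. The genes that rose most included COLEC11, a secreted lectin, by 4.23 ± 0.11 (adjusted p = 5.26e-09), RSRP1, an arginine- and serine-rich protein gene, by 4.09 ± 0.16 (adjusted p = 2.56e-08), and the pseudogene WFDC21P by 4.32 ± 0.63 (adjusted p = 0.0002). PTPRR and PTPN22, which encode tyrosine phosphatases, LRIT3, DCAF4L1 and CALHM4 were below background in DMSO. They were at least 11.7-fold, 6.25-fold, 10.6-fold, 6.7-fold and 8.99-fold higher with E7820. Normexp, whose offset draws dim genes toward 0, gave them log2 fold changes of only 1.66, 1.37, 1.85, 1.25 and 1.57, so these bounds depend on how dim signal is treated. CCNH, the cyclin of the CDK-activating kinase, fell by 4.18 ± 0.08 (adjusted p = 1.21e-09), R3HDM2 by 3.74 ± 0.09, SFXN2, a mitochondrial carrier, by 3.66 ± 0.14, GSTO2, a glutathione transferase, by 3.62 ± 0.12, and HACD1, a fatty acid elongation enzyme, had a log2 fold change of -3.525 ± 0.144. FBN3 and RNF157-AS1 fell below background, at least 9.41-fold and 3.87-fold lower (log2 -1.32 and -0.79 with normexp), and CFAP77, above background on part of the E7820 arrays, fell by 4.22 ± 0.28, or 2.09 with normexp.

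Genes of DNA replication and the S phase fell as a list, with 17 of 32 members lower and 2 higher (18 and 2 adjusted over the list alone), a median log2 fold change of -0.28 (-0.43 with median centring) and camera's adjusted p = 0.00247. CDC45, a replicative helicase subunit, fell by 2.49 ± 0.14, and the DNA polymerase α genes POLA1 and POLA2 fell by 1.76 ± 0.10 and 1.18 ± 0.19. AP-1 and immediate early genes rose, with 15 of 26 members higher and 2 lower in either count, a median of 0.43 and adjusted p = 0.00271. Among them JUN rose by 1.54 ± 0.10 and FOSB by 1.14 ± 0.11. The ATF4 and amino acid response list also rose, with 17 of 27 members higher and 6 lower in either count, a median of 0.61 and adjusted p = 0.00945. NUPR1, CHAC1 and ATF3 rose by 2.69 ± 0.17, 2.26 ± 0.16 and 2.19 ± 0.07, whereas ATF5 fell by 2.01 ± 0.17. With an estimated correlation these 3 lists had adjusted p = 0.947. Their medians on slide 1 and slide 2 were -0.30 and -0.27, 0.41 and 0.46, and 0.59 and 0.70.

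Cytosolic ribosomal protein genes shifted upward with 7 of 30 members higher and 0 lower (2 and 0 adjusted over the list alone), a median of 0.28 (0.25 on slide 1, 0.31 on slide 2) and adjusted p = 0.0242, and adjusted p = 0.947 with an estimated correlation. This call was lost without DMSO replicate 3, E7820 replicate 1 or E7820 replicate 2 (adjusted p 0.0675 to 0.097), and with quantile normalization, median centring, the deposited table and fry. Its adjusted p ranged from 6.38e-05 to 0.947 over the alternatives, and its median fell to 0.04 with quantile normalization, where RPL5 and RPL37 had values of 0.23 and 0.15. RPL5 rose by 0.48 ± 0.10 (adjusted p = 0.0016) and RPL37 by 0.38 ± 0.10 (adjusted p = 0.00797), calls that median centring ended (ranges over the alternatives, 6.73e-06 to 0.219 and 7.02e-05 to 0.405).

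The other 26 lists did not pass with E7820 (adjusted p 0.0535 to 0.925), and their counts adjusted over the list alone differed by at most 1. SR proteins and SR kinases had 7 members higher and 1 lower of 19. CLK4 and CLK1, kinases of SR proteins, rose by 1.21 ± 0.09 and 0.91 ± 0.11 and SRSF1 by 0.82 ± 0.10. Nonsense-mediated decay factors had 9 higher and 1 lower of 16. Both of these lists passed with slide as a block (adjusted p = 0.0284 and 0.0241) and with replicate number as a block (0.032 and 0.0254; ranges over the alternatives, 0.0197 to 0.947 and 0.00143 to 0.947). U2 snRNP and 3' splice site factors had 8 higher and 7 lower of 24. DDX46 and U2SURP, which act with the U2 snRNP, fell by 1.67 ± 0.09 and 1.52 ± 0.09. The hnRNP proteins had 8 higher and 8 lower of 23, with PTBP2, a splicing repressor of neuronal exons, higher by 2.00 ± 0.10. The p53 targets had 10 higher and 9 lower of 28 (adjusted p = 0.847), with XPC, TP53I3 and FDXR lower by 1.45 ± 0.18, 1.23 ± 0.16 and 1.12 ± 0.13. The interferon response had 2 higher and 10 lower of 26, with DDX60 lower by 1.61 ± 0.09. NF-kappaB targets had 8 higher and 1 lower of 16, with TNFAIP3 and CXCL1 higher by 1.38 ± 0.10 (0.91 with normexp) and 1.1 ± 0.11. This list passed with quantile normalization, no filter, the deposited table and fry (range of adjusted p over the alternatives, 0.00143 to 0.947), and without DMSO replicate 1, DMSO replicate 2 or E7820 replicate 3 (0.0256 to 0.0397). G2 and mitosis genes had 7 higher and 5 lower of 29, with TOP2A lower by 1.31 ± 0.07 and CENPF higher by 0.74 ± 0.09. The integrins had 3 higher and 2 lower of 13, with ITGA3 and ITGB4 lower by 1.66 ± 0.19 and 1.30 ± 0.10.

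Members higher and lower with E7820 numbered 8 and 2 of 16 in the RBM39 and ligase list, 8 and 9 of 26 among homologous recombination and Fanconi genes, 1 and 8 of 18 among replication-dependent histones, and 2 and 5 of 18 in endoplasmic reticulum stress. They numbered 6 and 4 of 14 among Wnt targets, 3 and 6 of 22 in cholesterol biosynthesis, 7 and 4 of 23 in hypoxia and glycolysis, 2 and 2 of 9 in the AHR response, and 5 and 5 of 20 among NRF2 targets. For carbonic anhydrases they were 2 and 1 of 8, for ribosome biogenesis 1 and 11 of 27, for oxidative phosphorylation 3 and 7 of 25, for apoptosis regulators 11 and 5 of 29, for heat shock 3 and 3 of 19, and for RNA interference 2 and 3 of 13. The interferon and histone lists passed with no filter and with fry, and ribosome biogenesis with quantile normalization and the deposited table (ranges of adjusted p over the alternatives, 0.00272 to 0.947, 0.00211 to 0.947 and 0.0428 to 0.947). With fry the AHR and heat shock lists passed as well (adjusted p = 0.0203 and 0.0302). Epithelial markers had 1 higher and 1 lower of 15. Fibroblast, endothelial and blood cell markers had 1 higher and 1 lower of the 8 tested of 20 listed. The median and mean had opposite signs in the U2 snRNP, G2 and mitosis, p53, Wnt, AHR and NRF2 lists.

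In total 7936 of 15188 genes passed with E7820, 3872 higher and 4064 lower, and 8679 had an unadjusted p under 0.05. With an absolute log2 fold change of at least 1 as well, 843 were higher and 1389 lower. Of the called genes 48.8% were higher, against 33% with median centring and 37.1% with spike-in scaling. The groups did not overlap for 57.8% of genes, against 10% by chance. Other splits of the same 6 arrays gave up to 8 called lists, against the 4 of the real split.

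The comparison of siRBM39 with non-target siRNA asked what follows a loss of RBM39 mRNA. EDN1, the endothelin 1 gene, rose by 5.03 ± 0.10 (adjusted p = 2.7e-09) and COLEC11 by 4.17 ± 0.11 (adjusted p = 5.71e-09). The immune receptor gene VSTM1 and LRIT3 were below background with non-target siRNA and at least 14.3-fold and 10.1-fold higher with siRBM39 (log2 2.24 and 1.94 with normexp). ALDH8A1, an aldehyde dehydrogenase, rose from below background as well, but with an SD of 3.419 over the siRBM39 arrays that came from siRBM39 replicate 2, so no fold is given. DLL3, a Notch ligand, FGF1, a fibroblast growth factor, and DYDC2 were at least 5.42-fold, 3.59-fold and 3.28-fold higher (log2 1.2, 1.08 and 1.07 with normexp). SFXN2 fell by 3.42 ± 0.14 (adjusted p = 5.34e-08), KCNQ1, a potassium channel, by 3.22 ± 0.12, and NUDT14, a nucleotide sugar hydrolase, by 3.02 ± 0.13. KIAA0319 and the noncoding RNA DGCR5 fell below background, at least 4.19-fold and 4.26-fold lower (log2 -0.93 and -1.04 with normexp). CFAP77, EMID1 and GATM, an enzyme of creatine synthesis, were above background on part of the siRBM39 arrays and had log2 fold changes of -4.18 ± 0.28, -3.46 ± 0.18 and -2.99 ± 0.27. With normexp these were -2.16, -1.91 and -1.09.

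The p53 targets rose with siRBM39: 21 of 28 members were higher and 0 lower (23 and 0 adjusted over the list alone), with a median log2 fold change of 0.78 and camera's adjusted p = 1.57e-08. TP53INP1 rose by 2.39 ± 0.10, the death receptor gene FAS by 2.03 ± 0.13, the antiproliferative gene BTG2 by 1.90 ± 0.12, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, by 1.83 ± 0.25. XPC, TP53I3 and FDXR had values of -0.08 ± 0.18, 0.09 ± 0.16 and 0.31 ± 0.13, of which FDXR passed with slide as a block (adjusted p = 0.000132; range over the alternatives, 0.000132 to 0.663). With spike-in scaling TP53I3 and FDXR turned to -0.27 and -0.05, and XPC passed as lower at -0.44 (adjusted p = 0.02; range over the alternatives, 0.02 to 0.827). AP-1 and immediate early genes rose, with 20 of 26 higher and 0 lower in either count, a median of 0.71 and adjusted p = 1.57e-06. EGR2, EGR1, JUN and FOSB rose by 3.07 ± 0.11, 1.93 ± 0.11, 1.76 ± 0.10 and 1.32 ± 0.11. NF-kappaB targets rose, with 9 of 16 higher and 0 lower (11 and 0 adjusted over the list alone), a median of 0.61 and adjusted p = 0.000609. BIRC3, CXCL1 and TNFAIP3 rose by 1.81 ± 0.09, 1.79 ± 0.11 and 1.68 ± 0.10. With an estimated correlation each of these 3 lists had adjusted p = 0.91. Their medians on slide 1 and slide 2 were 0.77 and 0.78, 0.71 and 0.66, and 0.62 and 0.60. Spike-in scaling lowered the 3 medians to 0.42, 0.35 and 0.25, and normexp lowered that of the NF-kappaB targets to 0.38 and TNFAIP3 to 1.08.

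**Figure D2:**
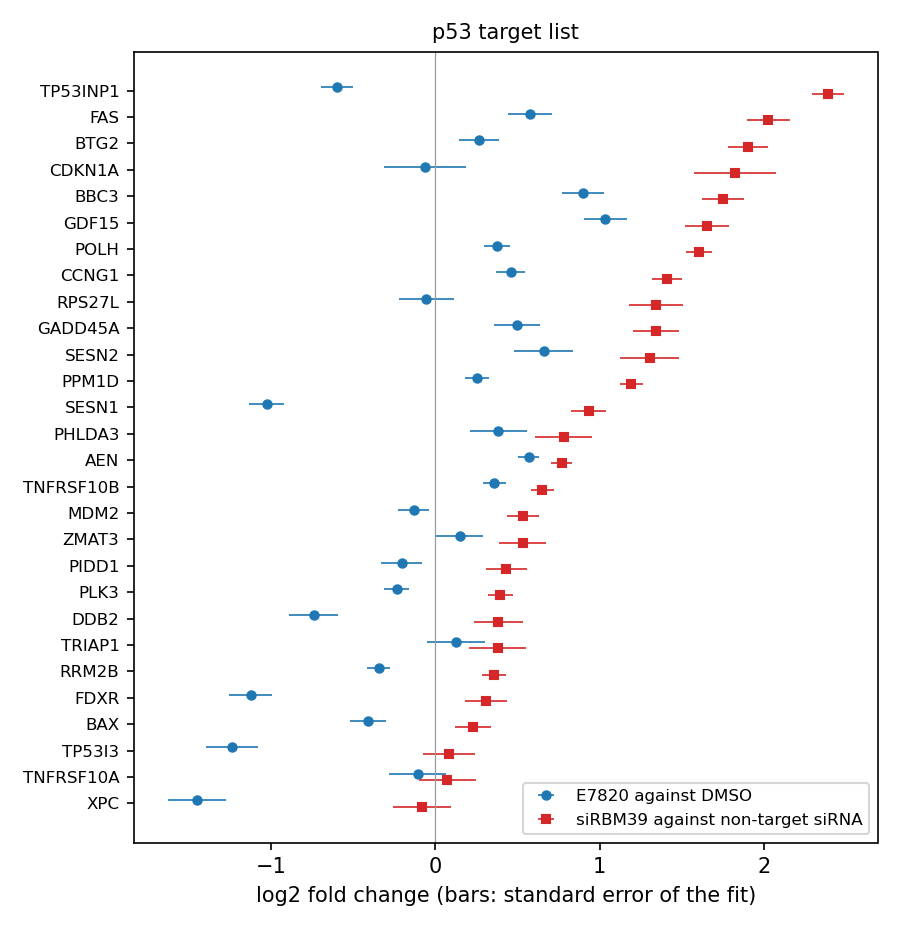
Log2 fold changes of the 28 tested p53 targets (x axis; bars, standard error of the fit, n = 3 per group) with E7820 and with siRBM39. With siRBM39 21 members passed as higher and 0 as lower, and with E7820 10 passed as higher and 9 as lower.

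S phase genes fell, with 20 of 32 members lower and 1 higher (21 and 1 adjusted over the list alone), a median of -0.38 and adjusted p = 0.00023. CDC45, POLA1 and POLA2 fell by 2.17 ± 0.14, 1.85 ± 0.10 and 1.14 ± 0.19. The interferon response fell, with 14 of 26 members lower and 2 higher in either count, a median of -0.43 and adjusted p = 0.00718. The viral RNA sensor gene DDX60 and OAS3 fell by 1.13 ± 0.09 and 1.01 ± 0.16. Both lists had adjusted p = 0.91 with an estimated correlation. Their medians on slide 1 and slide 2 were -0.35 and -0.42, and -0.45 and -0.33. The medians were -0.73 and -0.79 with spike-in scaling. That of the interferon response was -0.19 with normexp and -0.21 over probes above background on all 12 arrays, DDX60 fell by 0.75 with normexp, and OAS3 by 0.64 as the mean of its probes.

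Relative to the other genes, 3 more lists stood higher with siRBM39, and the medians of all 3 turned negative with spike-in scaling, which moved all genes down. G2 and mitosis genes had 11 of 29 higher and 3 lower in either count (median 0.27, and -0.09 with spike-in scaling; adjusted p = 0.0318). HMMR and CENPF rose by 1.15 ± 0.11 and 1.05 ± 0.09, and TOP2A fell by 0.61 ± 0.07. SR proteins and SR kinases had 9 of 19 higher and 1 lower in either count (median 0.30, and -0.06 with spike-in scaling; adjusted p = 0.0459), with SRSF8 and CLK4 higher by 1.42 ± 0.08 and 1.1 ± 0.09. Ribosomal protein genes had 8 of 30 higher and 1 lower, or 4 and 1 adjusted over the list alone (median 0.29, and -0.07 with spike-in scaling; adjusted p = 0.0318), and RPS19 fell by 0.68 ± 0.14. With spike-in scaling CENPF, TOP2A and RPS19 had values of 0.69, -0.96 and -1.04. All 3 had adjusted p = 0.91 with an estimated correlation, and slide medians of 0.29 and 0.26, 0.29 and 0.29, and 0.25 and 0.35. The G2 and mitosis call was lost without non-target siRNA replicate 3, siRBM39 replicate 1 or siRBM39 replicate 2 (adjusted p 0.0664 to 0.108), as was the ribosomal call (0.0664 to 0.173). The SR call was lost without non-target siRNA replicate 2 or 3 or siRBM39 replicate 1 or 2 (0.0535 to 0.106). Median centring ended all 3 calls, although the medians stayed at 0.26, 0.29 and 0.28. Quantile normalization ended those of the SR and ribosomal lists (medians 0.20 and 0.04), and the deposited table and fry that of the ribosomal list. For the 3 lists the adjusted p ranged over the alternatives from 0.0102 to 0.91, 0.00212 to 0.91 and 0.000223 to 0.91.

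The other 22 lists did not pass with siRBM39 (adjusted p 0.112 to 0.981), and their counts adjusted over the list alone differed by at most 3. Nonsense-mediated decay factors, with 4 higher and 0 lower of 16, passed with slide or replicate number as a block (adjusted p = 0.0477 and 0.0494; range over the alternatives, 0.00362 to 0.91). U2 snRNP factors had 7 higher and 7 lower of 24, with DDX46 and U2SURP lower by 1.12 ± 0.09 and 1.00 ± 0.09, and hnRNP proteins had 6 higher and 3 lower of 23, with PTBP2 higher by 1.51 ± 0.10. Cholesterol biosynthesis had 9 higher and 5 lower of 22, with HMGCS1 higher by 1.20 ± 0.09. The ATF4 list had 10 higher and 4 lower of 27, with NUPR1, ATF3 and CHAC1 higher by 2.36 ± 0.17, 1.60 ± 0.07 and 1.01 ± 0.16 (CHAC1 0.65 with spike-in scaling). The integrins had 5 higher and 4 lower of 13, with ITGB4 higher by 0.73 ± 0.10 (0.37 with spike-in scaling).

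Members higher and lower with siRBM39 numbered 4 and 2 of 16 in the RBM39 and ligase list, 5 and 11 of 26 among homologous recombination and Fanconi genes, 1 and 7 of 18 among histones, and 0 and 5 of 18 in endoplasmic reticulum stress. They numbered 8 and 4 of 14 among Wnt targets, 9 and 5 of 23 in hypoxia and glycolysis, 3 and 0 of 9 in the AHR response, 3 and 4 of 20 among NRF2 targets, and 1 and 4 of 8 among carbonic anhydrases. For ribosome biogenesis they were 3 and 10 of 27, for oxidative phosphorylation 2 and 8 of 25, for apoptosis regulators 10 and 2 of 29, for heat shock 6 and 2 of 19, and for RNA interference 5 and 3 of 13. Epithelial markers had 3 and 3 of 15, and fibroblast, endothelial and blood cell markers 2 and 3 of 8. The median and mean had opposite signs in the ligase, AHR, NRF2 and RNA interference lists. With fry the ATF4, integrin, Wnt, cholesterol, hypoxia, AHR, carbonic anhydrase, histone, apoptosis and heat shock lists passed with siRBM39 (adjusted p 0.000181 to 0.0355).

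**Figure D3:**
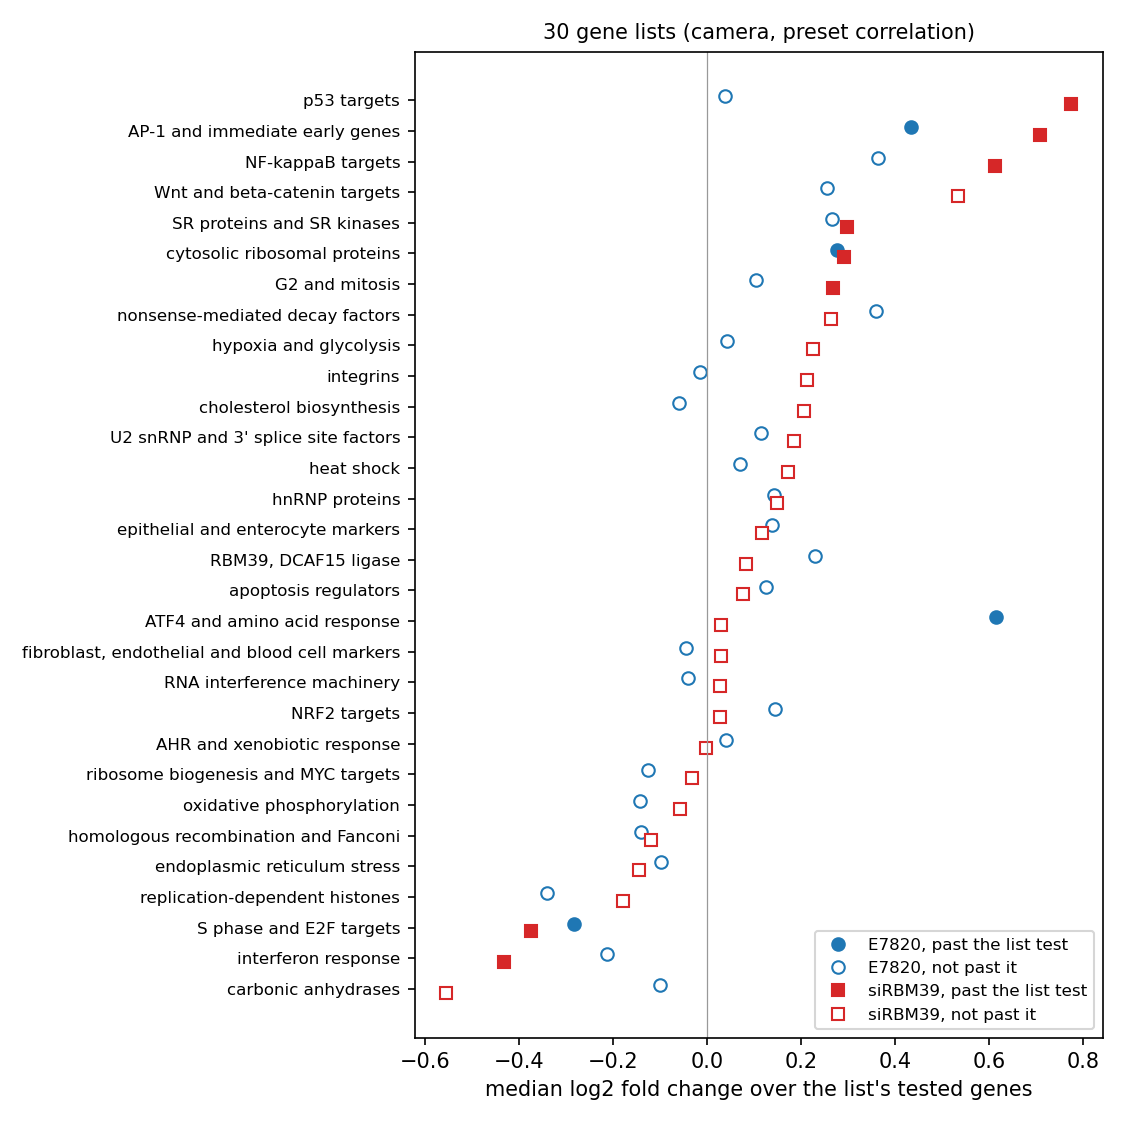
Median log2 fold change (x axis) over the tested members of each of 30 gene lists, for E7820 and siRBM39. Filled symbols mark the 4 and 8 lists past camera's adjusted p of 0.05 with the preset correlation.

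In total 7575 genes passed with siRBM39, 3708 higher and 3867 lower, and 8370 had an unadjusted p under 0.05. With an absolute log2 fold change of at least 1 as well, 808 were higher and 1090 lower. Of the called genes 49% were higher, against 18.7% with spike-in scaling. The groups did not overlap for 57.3% of genes, against 10% by chance.

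The responses to the compound and to the siRNA were set against each other to ask how far they coincide. LRIT3, COLEC11, DLL3, FGF1 and RSRP1 rose with both, and LRIT3, DLL3 and FGF1 were below background in both control groups, so no order of size is given. RSRP1 rose by 4.09 ± 0.16 with E7820 and 3.63 ± 0.16 with siRBM39, and DLL3 and FGF1 were at least 5.49-fold and 3.28-fold higher with E7820 (log2 1.14 and 1.07 with normexp). CFAP77, SFXN2, KIAA0319, KCNQ1 and DGCR5 fell with both, with KCNQ1 lower by 3.15 ± 0.12 with E7820 and by 3.22 ± 0.12 with siRBM39, and with KIAA0319 and DGCR5 at least 3.6-fold and 6.75-fold lower with E7820 (log2 -0.66 and -1.15 with normexp). Of 5578 genes called in both contrasts, 5205 (93.3%) had the same direction. There were 2482 genes higher in both, where independent lists would share 945, and 2723 lower in both, where they would share 1035. Genes with opposite calls numbered 192 and 181, against 986 and 992 for independent lists.

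Across the 15188 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.736 and Spearman's rho = 0.697, with a covariance of 0.395. Among the 2232 genes called with E7820 at an absolute log2 fold change of at least 1, r was 0.875, and 84.9% of them were called in the same direction with siRBM39. Of the genes called in both in the same direction 58.3% had the larger change with E7820. Taken within replicate numbers 1, 2 and 3, r was 0.68, 0.627 and 0.729.

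**Figure D4:**
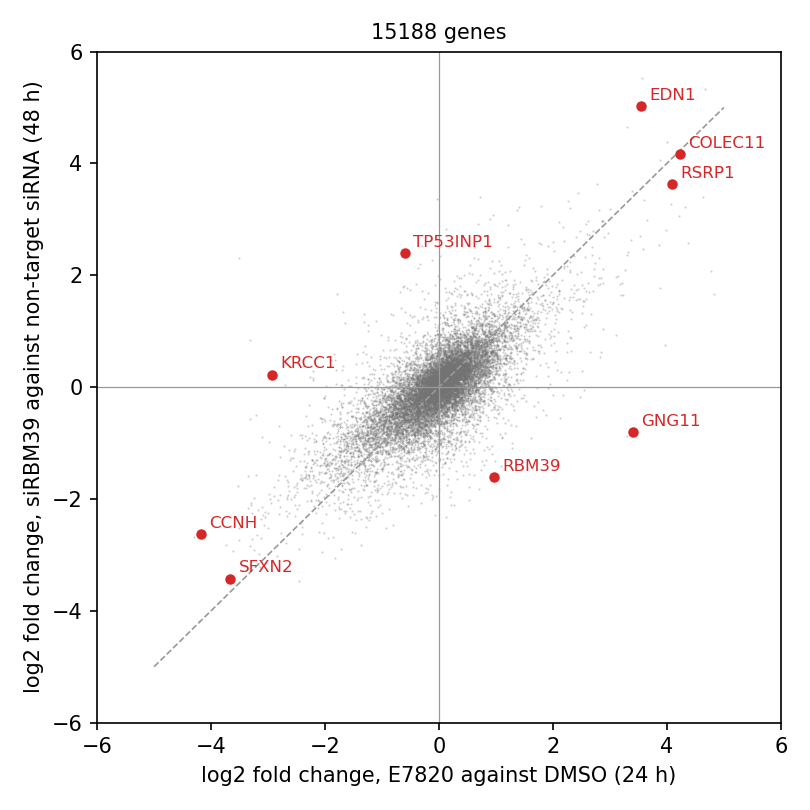
Log2 fold change with siRBM39 (y axis) against that with E7820 (x axis) for 15188 genes, with 9 named genes in red and the line of equal change dashed. The slope of siRBM39 on E7820 was 0.673, 76.4% of genes had the same sign in both, and RBM39, TP53INP1, KRCC1 and GNG11 lie far from the dashed line.

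The difference between the responses was tested as an interaction, in which the agent goes together with transfection and with 48 h against 24 h. RNF157-AS1 was at least 3.87-fold lower with E7820 and at least 3.05-fold higher with siRBM39 (adjusted p of the difference = 0.00119; log2 -0.79 and 0.76 with normexp), although the siRBM39 call was lost with the 6 arrays of that contrast alone (adjusted p = 0.0532; range over the alternatives, 0.0066 to 0.0532). CBS, the enzyme of cystathionine synthesis, fell by 1.78 ± 0.33 with E7820, partly below background, and rose by 1.67 ± 0.33 with siRBM39 (adjusted p of the difference = 0.00063), values that normexp brought to -0.62 and 0.98. TP53INP1 fell by 0.60 ± 0.10, or 0.34 as the mean of its probes, and rose by 2.39 ± 0.10 (difference 2.98, adjusted p = 1.6e-06). KRCC1 fell by 2.93 ± 0.09 with E7820 and had a value of 0.22 ± 0.09 with siRBM39, which passed with slide as a block (adjusted p = 0.0298; range over the alternatives, 0.0298 to 0.43) and turned to -0.14 with spike-in scaling, a difference of 3.15 (adjusted p = 1.31e-06). LEMD1 and SLC44A5, wholly or partly below background in 3 of the groups, also had higher values with siRBM39, the latter lost with normexp (adjusted p = 0.0719; range over the alternatives, 0.00425 to 0.0719). In the other direction KRTAP3-1 rose by 3.98 ± 0.12 with E7820 and by 0.75 ± 0.12 with siRBM39, or 0.40 with spike-in scaling (difference -3.22, adjusted p = 3.05e-06). GNG11, a G protein subunit, was at least 3.81-fold higher with E7820 and below background with siRBM39 (adjusted p of the difference = 3.05e-06), and PCDHB10, a protocadherin, was at least 2.3-fold higher with E7820 and below background in both siRNA groups (adjusted p of the difference = 4.38e-05). With normexp their differences were -0.97 and -0.83, so the sizes rest on the treatment of dim signal. PTPRR, PTPN22 and CLCA3P, each below background on arrays of more than 1 group, also had lower values with siRBM39. PTPN22's call was lost without E7820 replicate 3, siRBM39 replicate 1 or siRBM39 replicate 2 (adjusted p 0.0504 to 0.0542) and with quantile normalization and the deposited table (range over the alternatives, 0.00145 to 0.0639).

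The p53 targets differed as a list, with 21 of 28 members higher with siRBM39 than with E7820 and 0 lower (23 and 0 adjusted over the list alone), a median difference of 0.85 (0.92 on slide 1, 0.76 on slide 2) and adjusted p = 1.21e-13. The difference was 1.89 for CDKN1A, 1.45 for FAS and 1.64 for BTG2. The ATF4 list was lower with siRBM39, with 11 of 27 members lower and 2 higher (12 and 2 adjusted over the list alone), a median of -0.33 (-0.28 on slide 1, -0.51 on slide 2, -0.20 with median centring) and adjusted p = 0.00205. G2 and mitosis genes were higher, with 5 of 29 members higher and 0 lower in either count, a median of 0.31 (0.35 on slide 1, 0.23 on slide 2) and adjusted p = 0.0117. This call was lost without E7820 replicate 3 (adjusted p = 0.0549) and with median centring and fry (range over the alternatives, 0.000856 to 0.955). With median centring the median itself was larger, at 0.45. Cholesterol biosynthesis was higher, with 7 of 22 members higher and 1 lower (8 and 1 adjusted over the list alone), a median of 0.38 (0.41 on slide 1, 0.25 on slide 2) and adjusted p = 0.0359. It was lost without DMSO replicate 1 or 2, E7820 replicate 2 or 3, or siRBM39 replicate 1 (adjusted p 0.0552 to 0.0669), and under 5 of the alternatives other than estimated correlation (range, 0.0157 to 0.955). With an estimated correlation all 4 lists had adjusted p = 0.955. The other 26 lists did not pass (adjusted p 0.143 to 0.929). In total 3216 genes differed, 1808 higher and 1408 lower with siRBM39, and 4981 had an unadjusted p under 0.05. With slide as a block 6974 genes passed, and with replicate number as a block 6795.

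Probes of the same gene were compared because RBM39 is a splicing factor and probes can lie on different transcripts. In ATAT1, the α-tubulin acetyltransferase gene, 1 probe rose by 3.03 with E7820 and 2.70 with siRBM39 while the other fell by 1.12 and 1.02. In CENPN, a kinetochore gene, 1 of 3 probes rose by 3.14 and 2.82 while the brightest had values of -0.30 and -0.21. In MAP7D3, a microtubule-binding protein gene, 1 of 3 probes fell by 2.21 and 1.83 while another rose by 0.49 and 0.60. PHF20L1 and ERVMER34-1 had probes moving in opposite directions in both treatments. The largest of the diffSplice adjusted p for these 5 genes was 1.23e-12. Among 3963 genes with at least 2 kept probes, 1068 passed with E7820 and 925 with siRBM39. With slide as a block the counts were 1727 and 1535, and with replicate number as a block 1701 and 1524. There were 693 genes called in both treatments, against 249 for independent lists, and in 619 of them the same pair of probes stood furthest apart in the same order. Of the 693 genes 480 had only 2 probes, so that the pair was fixed and the order alone could vary, and 98.8% of these had the same order.

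**Figure D5:**
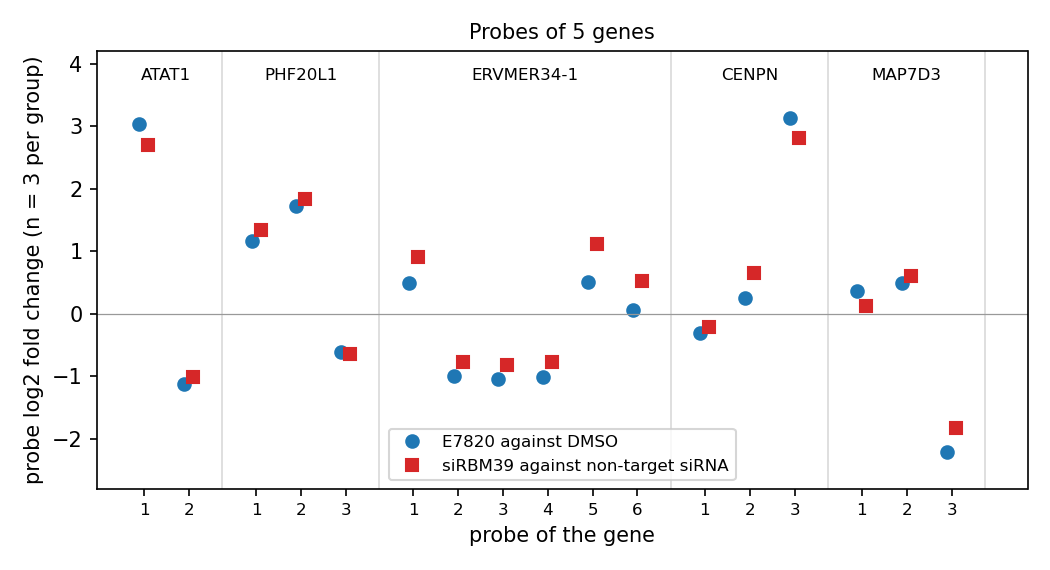
Log2 fold change (y axis, n = 3 per group) of each kept probe of 5 genes with E7820 and with siRBM39. The probes of a gene lie apart in both treatments, as in ATAT1, where the values are 3.03 and 2.70 on 1 probe and -1.12 and -1.02 on the other.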

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

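The tests of RBM39 below, on its probes and on scaling, were chosen after the result was seen. The groups hold 3 arrays each, so no array was tested for lying apart from its group.

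The p53 targets responded differently to the treatments, by a test of the difference: the median of siRBM39 minus E7820 was 0.846 (adjusted p = 1.21e-13, but 0.955 with an estimated correlation). The tables argue against a lower control level, since non-target siRNA minus DMSO had a median of -0.106 where siRBM39 gave 0.775. The SE beside the -0.106, 0.068, was taken over the genes of the list as if they were independent. It holds no spread between arrays. They argue also against an effect of 1 slide, since the lower of the slide medians was 0.755 and the higher 0.916. Time, transfection and agent cannot be told apart for the 0.846, because the design changes them together.

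RBM39 mRNA was higher with E7820 and lower with siRBM39, with a tested difference of -2.575. A single aberrant probe is argued against by the lowest of 3 probes, at 0.958 (SE 0.098). Scaling of the arrays is argued against by the lowest value over the scaling alternatives, 0.815 with median centring. Limma's adjusted p was at most 0.00231 over the alternatives. The SE used in this test, 0.094, was that of the main fit and not of median centring. A response of RBM39 transcripts to loss of the protein stays open and was not tested, since the arrays measured no protein.

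Probes of the same gene moved apart in both treatments in 693 genes. In 210 of the 693 (30.3%, exact 95% interval 26.9 to 33.9) probes were called in opposite directions with E7820. For these 210 genes that argues against unequal response of probes to 1 change of the gene. For the rest of the 693 unequal response stays open. Binding of other transcripts to a probe was not tested. Genes with probes on different accessions were over-represented among the 693, with an odds ratio of 2.26 (95% interval 1.9 to 2.7, Fisher's exact p = 7.13e-20). Of 1038 such genes 27.1% were called in both treatments, and of 2925 genes with probes on 1 accession 14.1% were. That test did not allow for the number of probes per gene. Different transcripts of the same gene could therefore lie behind part of the pattern. Splicing itself was not measured.

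Whether the counts could come from the arrays' grouping alone was tested on other splits of the same arrays, and 10 splits are too few for a share under 0.05. For genes, 1 of the 10 splits with E7820 reached the real 7936 (the real split, highest other 18), and 1 of 10 with siRBM39 reached 7575 (highest other 0). For probes of the same gene, 1 of 10 reached 1068 with E7820 (highest other 5) and 1 of 10 reached 925 with siRBM39 (highest other 0). For gene lists, 5 of 10 reached the real 4 with E7820 (highest other 8), and 1 of 10 reached 8 with siRBM39 (highest other 6). For the difference, splits were made of the differences within replicate numbers, a fit that gives 6372 genes in place of the 3216 reported, and 1 of 10 reached that count (highest other 0). For the overlap, 1 of 100 splits reached the 5205 shared genes (highest other 2). Other splits of a contrast called at most 18 genes and so could share hardly any. This count therefore repeats those of the single contrasts, and no conclusion is drawn from it. For the correlation, 1 of 100 reached 0.736, but the highest other was 0.731, in a split that put both slide 2 arrays on the same side. A split that did not, and that kept the real siRBM39 groups, reached 0.672. The SD of r over replicate numbers was 0.0511, so no conclusion on grouping by chance is drawn from this rank. The real groups are balanced over the slides, and the correlation was 0.704 on slide 1 alone, which argues against the slide as its source.

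The following values stand out because a test of the difference between the responses passed, with siRBM39 minus E7820 given on the log2 scale. The responses differed for 3216 genes. Median differences were 0.311 for G2 and mitosis, -0.334 for ATF4 and amino acid response and 0.379 for cholesterol biosynthesis, and with an estimated correlation all 3 had adjusted p = 0.955. The ATF4 median was -0.2 with median centring. The G2 and mitosis call was lost also with median centring (median 0.446), with fry and without E7820 replicate 3. The cholesterol call was lost under 5 other alternatives and without any of 5 arrays. For RNF157-AS1, LEMD1, CBS, SLC44A5, FBN3, EMID1, VSTM1, GNG11, PCDHB10, PTPRR, PTPN22, CLCA3P, CALHM4 and DCAF4L1, at least 1 group was wholly or partly below background, so their values below are not measured sizes and their order is not a ranking. Normexp brought these 14 toward 0, as to 1.55 for RNF157-AS1, 0.365 for FBN3, -0.974 for GNG11 and -0.832 for PCDHB10. Genes higher with siRBM39 by at least 1.5 were RNF157-AS1 (5.818), LEMD1 (4.169), CBS (3.45), KRCC1 (3.151), SLC44A5 (3.019), TP53INP1 (2.984), EGR2 (2.129), ITGB4 (2.03), EGR1 (1.916), CDKN1A (1.888), HACD1 (1.757), BTG2 (1.636), FBN3 (1.632), CCNH (1.544) and ITGA3 (1.514). Smaller positive values belonged to EDN1 (1.486), FAS (1.451), ATF5 (1.449), BIRC3 (1.434), FDXR (1.43), XPC (1.367), VSTM1 (1.347), TP53I3 (1.319), SRSF8 (1.285), HMMR (1.017), HMGCS1 (0.926), R3HDM2 (0.911), TOP2A (0.708), CXCL1 (0.69), GSTO2 (0.682), DDX46 (0.55), U2SURP (0.522) and DDX60 (0.488). Negative values belonged to GNG11 (-4.219), PCDHB10 (-4.168), KRTAP3-1 (-3.223), PTPRR (-3.166), PTPN22 (-2.704), CLCA3P (-2.685), CALHM4 (-1.798), CHAC1 (-1.249), DCAF4L1 (-1.235), EMID1 (-1.002), RPS19 (-0.988), RBM23 (-0.59), ATF3 (-0.589) and PTBP2 (-0.489).

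Some of these calls lay near the threshold and were lost when 1 array, whichever of many, was left out. With all arrays limma's adjusted p was 0.0416 for CALHM4, 0.0286 for RBM23 and 0.0336 for PTBP2. CALHM4 was lost without any 1 of 10 arrays (adjusted p 0.0528 to 0.0873). RBM23 was lost without any 1 of 8 (0.0502 to 0.0719) and PTBP2 without any 1 of 7 (0.0603 to 0.084). Median centring ended the calls of 14 of the 48 differences named, those of ATF3, CALHM4, CHAC1, CXCL1, DCAF4L1, DDX46, DDX60, EMID1, GSTO2, PTBP2, RBM23, RPS19, TOP2A and U2SURP. The differences themselves stayed. Positive ones grew, as for TOP2A from 0.708 to 0.842, and negative ones shrank, as for ATF3 from -0.589 to -0.455. Normexp ended 5 (DCAF4L1, EMID1, FBN3, SLC44A5, VSTM1), spike-in scaling 4 (CXCL1, DDX46, DDX60, U2SURP), no filter 3 (CALHM4, PTBP2, RBM23), and quantile normalization and the deposited values each the same 2 (EMID1, PTPN22).

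Probes without a gene symbol, which the comparisons did not use, carried signal as well. Of the 8037 kept, 2492 passed with E7820 and 2169 with siRBM39, 1487 of them in both and in the same direction.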

How the results depend on the processing

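Scaling to spike-in probes, slide 1 alone, and every probe counted by itself were chosen after the data were seen. Of 1032 fold changes of named genes with an array left out, 1005 kept their call, 24 became weaker and 3 stronger, and of 2016 under other alternatives 1930 kept it, 35 became weaker, 40 stronger and 11 reversed. For gene differences the counts were 1014 of 1044 kept with an array left out (28 weaker, 2 stronger) and 879 of 934 under other alternatives (30 weaker, 24 stronger, 1 reversed). For list tests they were 694 of 720 (19 weaker, 7 stronger) and 829 of 900 (34 weaker, 37 stronger). Of the main counts and values 91 of 96 and 117 of 143 kept within their limit, which for counts is 1.5 times the main count, so that 5295 genes with E7820 under median centring (main 7936) lay within it. RBM39 kept its direction throughout, at 0.909 to 1.024 with E7820 and -1.683 to -1.552 with siRBM39 with an array left out. The share of probes above background, lowest on siRBM39 replicate 2 at 45.9%, limits what dim genes can show.

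Median centring gave 4785 genes with siRBM39 (main 7575), 862 for the difference (3216), 3043 shared genes (5205), 687 and 555 genes for probe usage (1068 and 925), and 5 lists with siRBM39 (8) and 2 for the difference (4); the cause was not tested. Replicates 1 and 2, both on slide 1, differed with an SD of 0.185 to 0.28 in DMSO, E7820 and siRBM39. Either of them differed from replicate 3, on slide 2, with an SD of 0.387 to 0.442. For non-target siRNA the values were 0.42 against 0.433 and 0.493. Both blocks take spread between replicate 3 and the others out of the residual. A slide block gave 6974 genes for the difference and 1727 and 1535 for probe usage, and a replicate block 6795, 1701 and 1524. Beyond these and the calls named beside their results, a block ended no call and made calls of BTG2, RPS19 and SRSF8 with E7820, of CENPN's brightest probe with both treatments, and of the differences of CDC45, CENPF, CLK1, CUL4A, DDB1, DYDC2, ERVMER34-1, ITGA2 and RSRP1 (CENPF and DYDC2 with the slide block alone). Among the named genes and the lists it changed no other call, while the counts of genes rose to 10744 with E7820, 10536 with siRBM39 and 7603 shared with the slide block. Slide 1 alone, where the spread between slides is absent, gave 5567 genes for the difference. Every probe counted by itself gave 12676 and 11726 probes and 8101 shared, out of 28423. These include 8037 probes without a symbol, which the gene counts left out, and a gene can count more than once. A fold change of at least 1 left 2232 and 1898, by construction. With no filter on dim probes the correlation was 0.65 and 9 lists passed with E7820. An estimated correlation left 0 lists for E7820, 0 for siRBM39 and 0 for the difference, and fry gave 10 with E7820 and 18 with siRBM39. The first of these 2 settings changed only the correlation. For the lists called in the main test it was estimated at 0.188 (ATF4) to 0.91 (ribosomal proteins), in place of the preset 0.01. Fry does not compare a list with other genes. The cause of the list count with no filter was not tested.

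With an array left out, which leaves fewer arrays, genes ranged over 6986 to 7958 with E7820, 6642 to 7193 with siRBM39 and 2521 to 3567 for the difference, shared genes over 4655 to 5305, the correlation over 0.709 to 0.736, and probe usage over 875 to 1047 and 747 to 861. Lists ranged over 3 to 7 with E7820 (7 without DMSO replicate 2), 5 to 8 with siRBM39 (5 without non-target siRNA replicate 3, siRBM39 replicate 1 or siRBM39 replicate 2) and 2 to 4 for the difference (2 without E7820 replicate 3).

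Taking the mean of a gene's probes reversed ATAT1 (0.955 with E7820, 0.84 with siRBM39), CENPN (1.029, 1.086), MAP7D3 (-0.454, -0.369), PHF20L1 (0.764, 0.846) and ERVMER34-1 with siRBM39 (0.028), since a CENPN probe other than the brightest rose and probes of the other 4 genes moved in opposite directions. Spike-in scaling, which moved every gene by -0.125 with E7820 and -0.358 with siRBM39, reversed CUL4A (-0.146) and RBM23 (-0.294) with siRBM39, and turned the sign of uncalled values of DCAF15 (-0.042), DDA1 (-0.257), FDXR (-0.051), KRCC1 (-0.137) and TP53I3 (-0.273) with siRBM39 and EGR1 (-0.11) with E7820. Normexp reversed the difference of KCNQ1 (0.391); the cause was not tested.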

Other observations

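The families were defined by symbol stem, and their test was written before its result was seen. Of 112 stems with at least 15 genes tested, 3 passed camera in both treatments and in the same direction. Signal rose for the small nucleolar RNA genes of the SNORD stem (115 genes). With E7820 76 were higher and 3 lower, with a median of 0.57 (0.65 on slide 1 and 0.38 on slide 2) and adjusted p = 7.27e-11. With siRBM39 61 were higher and 5 lower, with a median of 0.46 (0.54 and 0.42) and adjusted p = 5.33e-08. Spike-in scaling lowered these SNORD medians to 0.444 and 0.101. The small nucleolar RNA genes of the SNORA stem (100 genes) did not pass camera (adjusted p = 0.0559 with E7820 and 0.202 with siRBM39). Of them 42 were higher and 15 lower with E7820, and 41 and 21 with siRBM39. The related SCARNA stem (21 genes) did not pass either, with medians of -0.262 with E7820 and 0.308 with siRBM39. The small nucleolar RNA host genes (SNHG, 17 genes) had 15 higher and 0 lower with E7820 (median 0.815). They passed camera there (adjusted p = 6.96e-06, or 0.0561 with an estimated correlation). With siRBM39 9 were higher and 0 lower (median 0.326, adjusted p = 0.0662). Whether the SNORD probes read the small RNAs or longer transcripts that contain them was not tested. Zinc finger genes (ZNF, 408 genes) stood higher, with 203 higher and 52 lower with E7820 (median 0.42; 0.43 on both slides; adjusted p = 4.62e-07) and 197 higher and 53 lower with siRBM39 (median 0.36; 0.35 and 0.39; adjusted p = 2.82e-06). With spike-in scaling the siRBM39 median of the ZNF genes was -0.003. Genes of the RPL stem (62 genes) had 19 higher and 1 lower with E7820 (median 0.28, adjusted p = 0.00286). With siRBM39 23 were higher and 1 lower (median 0.28, adjusted p = 0.00862). The RPS stem (46 genes) did not pass camera (adjusted p = 0.529 with E7820 and 0.506 with siRBM39). It had 8 higher and 7 lower with E7820, and 11 and 7 with siRBM39. Grouping was by symbol alone, so these stems need not hold ribosomal protein genes only. The RPL medians fell to 0.05 and 0.04 with quantile normalization, and with spike-in scaling to 0.158 and -0.077. With an estimated correlation none of these 3 families passed (adjusted p = 0.998 with E7820 and 1 with siRBM39).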
